A study of Mus musculus with 9 samples.

How the data were processed

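Expression was measured on 9 Affymetrix Mouse Gene ST 1.0 arrays, with 3 arrays of YFP-positive and 3 of wild-type sorted cells, 2 of total marrow and 1 of YFP-negative sorted cells. Sorted samples held 1800 to 10000 cells, the YFP-negative sample held 2300 cells, and total marrow entered as 10 ng of RNA. Per the labels, RNA was amplified with the NuGEN Ovation Pico WTA System V2, and the processing tools named are Affymetrix Expression Console 1.3.1 and RMA. The deposited values are log2 signals, 1 per transcript cluster and array, made by the authors with RMA (background correction, quantile normalization and a summary over the probes of a cluster). It is not stated whether all arrays were summarised together. A quantile normalization of all arrays together would give them near-equal distributions. The YFP-negative array did not share the distribution of the others (quartiles 2.68 and 5.07 over the rows tested), which argues against a common summary for that array.

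The values of the YFP-negative array lay below those of the other 8 arrays. Its median over the rows tested was 3.46, against 4.51 to 4.60 in the others, and the median change of all rows was −0.91 against YFP-positive, −0.88 against wild type and −0.85 against total marrow. Comparisons without that array used the values as deposited. For the 3 comparisons with it, the text reports values after cyclic loess normalization of the 9 arrays, a choice made after the data and the counts under all rescalings had been seen. Of the rescalings tried, cyclic loess gave the fewest calls in each of these comparisons; the counts under the others stand beside it. The genes named by the rule below overlapped between deposited and loess values for 8 of 10 higher and 4 of 10 lower genes against YFP-positive, for 7 and 5 against wild type, and for 10 and 9 against total marrow.

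The file holds 35556 rows. The 21789 rows that pair with exactly 1 gene symbol were tested, without a filter on intensity, and represent 19938 genes; 1621 rows with several genes and 12146 rows with no gene were left out of the main tests. Symbols came from the platform annotation, and 21698 of its Entrez identifiers matched the reference gene table (assembly GRCm38.p6), with 0 symbols changed. For the 999 genes with several rows, gene lists and named genes used the row with the highest mean over the 9 arrays. No named gene that was called had another row called in the opposite direction. No coordinates were used.

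All 9 arrays entered a single limma fit (limma 3.58.1, R 4.3.3; lmFit with a mean per group, eBayes with default settings), with 5 residual and 2.50 prior degrees of freedom on deposited values. Tests were two-sided. P-values were adjusted by the Benjamini-Hochberg method over all rows tested, and a row was called at an adjusted p under 0.05; counts of genes called are counts of such rows. Changes are log2 differences with the standard error (SE) from limma. Where only the lower group stands below the median of all values (4.43 as deposited, 4.53 after cyclic loess), a change against it is read as a lower bound on that scale. Where both groups stand below it, the size of the change is not resolved. That median is a stated cut, not a measured detection limit. The YFP-negative group has 1 array, so its spread was assumed to be that of the other groups, and any batch of that array cannot be told apart from its group. Labels do not say whether replicates are separate animals; the p-values therefore measure the spread between samples of a group, which may be technical only. Depth has no counterpart on arrays, so the number of arrays limits the precision.

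A set of 30 gene lists (511 genes, of which 469 were measured) was tested with limma's camera at its preset correlation of 0.01 between genes, with adjustment over the lists of a comparison. The correlation estimated for each list was the alternative. Members were also counted with p-values adjusted over the list alone. Genes were named by rule: the 10 largest changes in each direction among called genes whose 2 groups did not overlap, leaving out predicted genes, small RNAs and immunoglobulin or T cell receptor segments; or, where no gene was called, the 5 smallest p-values in each direction. The rule also named Il7, Icam1, Enpep, Ptprc, Nid1 and Nid2 in every group, and up to 4 called members of each list, or up to 2 members where none was called. Members that moved against the rest of their list, the genes behind counts of 5 or fewer, and the sex-linked genes are named beyond that rule, after their values were seen. The lists, the rule, the groups, the tests and the first set of alternatives were fixed before the data were examined.

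On simulated data of 19938 genes, the fit recovered 94.5% of 200 genes changed by 2 log2 units between YFP-positive and total marrow, 93% between wild type and total marrow, 96.5% between YFP-positive and wild type, and 84% between YFP-negative and YFP-positive. At 1 log2 unit the shares were 48%, 47%, 64.5% and 0%. With genes drawn independently of each other, a simulated shift of a list between YFP-positive and wild type was called. Of 100 unshifted lists, 1 had a p under 0.05. The simulation held no correlation between genes, so it does not test whether the preset correlation is adequate.

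Alternatives were median centring, quantile and cyclic loess normalization, a filter on dim rows (above the median of all values in at least 2 arrays), all rows of the file, 1 row per gene, eBayes with trend and robust, array weights, a fit on only the groups compared, a minimum 2-fold change, the replicate number as a block, camera on ranks, and leaving out each replicate in turn. Repeating them from the loess values, and giving each of the sorted groups its own total marrow array, were added after the data were seen. Pearson correlations between arrays are across genes, which are not independent replicates.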

Results

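Stromal cells that produce interleukin 7 were profiled from mouse bone marrow, where Il7 is a growth factor for B cell precursors. In Il7-Cre/Rosa-eYFP mice, YFP marks cells in which a Cre driven by Il7 is or has been active. Sorted cells lacked CD45, the leucocyte antigen encoded by Ptprc, and lineage markers, and carried CD54 (Icam1) and BP1 (Enpep). 3 arrays held YFP-positive cells of this gate, 1 array held its YFP-negative cells from the same reporter strain, and 3 arrays held cells of the gate from C57BL/6J mice, here called wild type. Total marrow on 2 arrays served as the control. Sorted mice were 6 to 12 weeks old. Each array gave a log2 signal for 21789 rows with 1 gene, and the median signal was 4.51 to 4.60 in 8 arrays and 3.46 in the YFP-negative array.

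**Figure D1:**
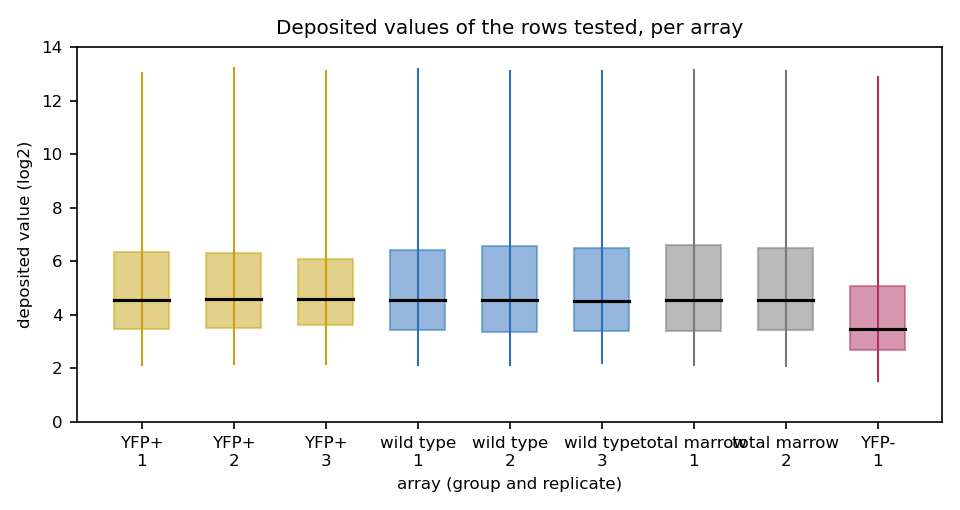
Deposited log2 values of the 21789 rows tested, for each of the 9 arrays; boxes span the quartiles, black lines mark the medians and vertical lines run from the lowest to the highest value. The YFP-negative array has a median of 3.46, below the 4.51 to 4.60 of the other 8 arrays.

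The sorted arrays resembled each other far more than they resembled total marrow. Across genes, the correlation was 0.950 to 0.974 between YFP-positive and wild-type arrays, and 0.780 to 0.817 between either group and total marrow. It was 0.981 to 0.987 among wild-type arrays, 0.950 to 0.966 among YFP-positive arrays and 0.993 between the total marrow arrays. The YFP-negative array correlated at 0.937 to 0.943 with wild type, 0.920 to 0.940 with YFP-positive and 0.766 to 0.768 with total marrow. YFP-positive replicate 3 had the lowest quality weight of the 9 arrays, 0.311, where the highest was 1.69.

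The gate transcripts Enpep, Icam1 and Ptprc followed the sort, and Il7, which drives the reporter, was higher in the sorted groups than in total marrow. Il7 (transcript cluster 10497188) stood at 7.21 ± 0.74 (SD, n = 3) in YFP-positive cells and 7.82 ± 0.24 (SD, n = 3) in wild-type cells, against 3.30 ± 0.15 (SD, n = 2) in total marrow. Enpep (10502081) stood at 6.77 ± 0.92 and 7.36 ± 0.16 against 4.05 ± 0.08, and Icam1 (10583519) at 6.50 ± 0.31 and 6.41 ± 0.18 against 5.35 ± 0.05. Ptprc (10358224) stood at 3.75 ± 0.08 and 3.65 ± 0.05 against 9.72 ± 0.04. After cyclic loess normalization the YFP-negative array held Il7 at 7.03, Enpep at 6.81, Icam1 at 6.66 and Ptprc at 3.86. On that scale Il7 averaged 7.16 in YFP-positive and 7.58 in wild-type cells, so it did not follow the YFP gate. As deposited the YFP-negative array held Il7 at 5.87.

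**Figure D2:**
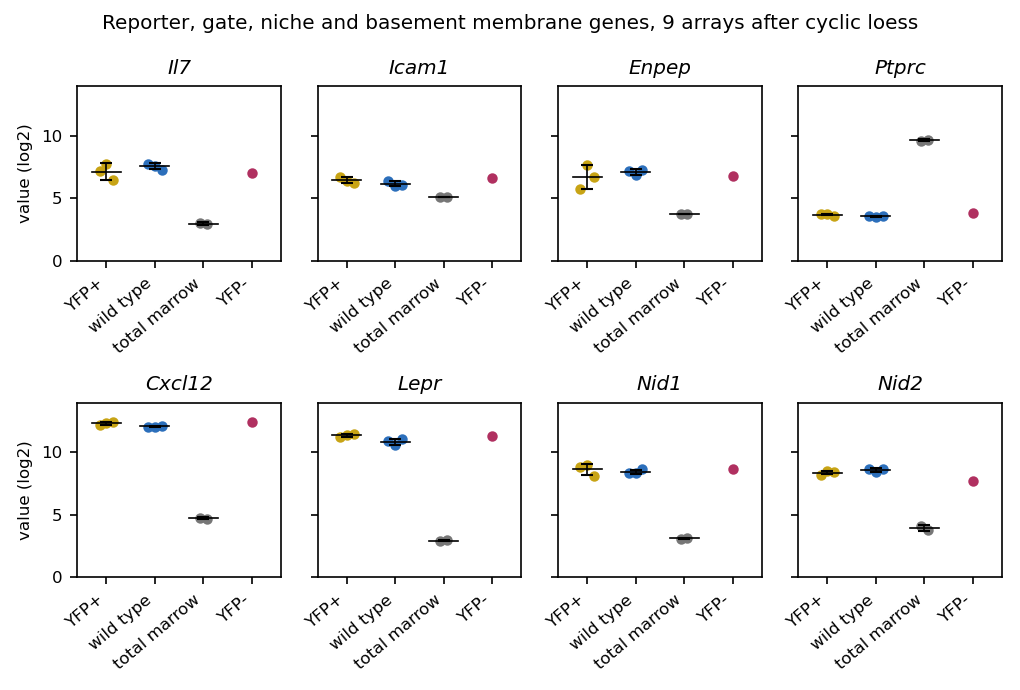
Log2 values after cyclic loess normalization of 8 genes in the 9 arrays; points are arrays, bars are group means with SD, and the YFP-negative group is a single point. Il7, Enpep, Cxcl12, Lepr, Nid1 and Nid2 are high in every sorted array and low in total marrow, and Ptprc is the reverse.

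YFP-positive cells were set against total marrow to ask which genes separate Il7-reporter stroma from the marrow as a whole. Input differs along with the cells, 10 ng of RNA for total marrow and 1800 to 10000 cells for these samples. Lepr, Kitl, Igfbp5 and Sfrp4 were also higher in the YFP-negative array than in total marrow. The comparison therefore does not single out the reporter-marked cells of the gate. The cells were rich in the transcripts of perivascular reticular stroma. Lepr, the leptin receptor, was higher by 7.84 ± 0.12 log2 units (SE, n = 3 and 2, adjusted p = 5.19e-08), and Cxcl12, a chemokine that holds haematopoietic cells in the marrow, by 6.90 ± 0.11 (SE). Igfbp5, which binds insulin-like growth factors, was higher by 8.41 ± 0.24 (SE). Cyp1b1 (7.92), the complement inhibitor Serping1 (7.86), the Wnt modulator Sfrp4 (7.62), the matrix gene Tnc (7.60), the BMP antagonist Chrdl1 (7.55), Gdpd2 (7.41), Kitl, which encodes stem cell factor (7.35), and the bone sialoprotein gene Ibsp (7.33) also rose. Genes of granulocytes and other leucocytes were lower, led by Ly6g (−7.66), Retnlg (−7.54), Ifitm6 (−7.45), Cd52 (−7.40), Mmp8 (−7.28), Pglyrp1 (−7.21), Chil3 (−7.19), Cd53 (−7.16), Ltf (−6.88) and Lcn2 (−6.80). Il7 was higher by 3.91, Enpep by 2.71 and Icam1 by 1.16, and Ptprc was lower (−5.97).

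In all, 2396 rows were higher and 4026 lower in YFP-positive cells than in total marrow; 1435 and 2948 of them changed by at least 2-fold. Leaving out total marrow replicate 1 or 2 reduced the total of 6422 to 3636 or 4179. The 10 higher genes named first by their change, from Igfbp5 to Ibsp, stood at 3.29 to 4.40 in total marrow, below the median of all values (4.43), so their changes are lower bounds and their order is not resolved.

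The stromal lists rose together in YFP-positive cells. Members are given as called over all genes and, in parentheses, as higher/lower when adjusted over the list alone. Of 16 measured reticular mesenchymal markers 13 were higher and 1 lower (13/1), with a median change of 5.55; Snai2 (6.63), Pdgfrb (6.60) and Ebf3 (6.45) rose with Lepr, while Thy1 was lower (−3.34). Of 15 haematopoietic niche factors 12 were higher and 1 lower (12/1), among them Kitl, Cxcl12, Bmp4 (5.90) and Il34 (5.01), while Lgals1 was lower (−1.26). Osteogenic markers rose in 10 of 14 (11/0), with Phex at 5.44, Dlx5 at 5.06 and the parathyroid hormone receptor Pth1r at 3.61. Adipogenic markers rose in 7 of 13 and fell in 1 (7/1); adiponectin (Adipoq) was at 7.08, Agt at 6.32, Lpl at 4.84 and the regulator Pparg at 2.85, and Dgat2 was lower (−2.23). Only 3 of 14 chondrogenic markers were called (3/0), Comp (2.15), Sox9 (0.98) and Col11a1 (0.73), and the list's call (adjusted p = 0.0414) ended with an estimated correlation (adjusted p = 0.231) and after cyclic loess (adjusted p = 0.0839). That call also ended without YFP-positive replicate 2 (0.0538) or 3 (0.0829) or total marrow replicate 1 (0.0774).

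Lists of matrix and signalling genes rose as well. Basement membrane components rose in 15 of 18 (16/0): the nidogens Nid1 (5.13) and Nid2 (4.04) and the laminin chains Lamb1 (4.88), Lamc1 (4.51) and Lama4 (4.12). Interstitial matrix rose in 18 of 23 and fell in 1 (19/1), with Pcolce (7.06), Ogn (6.87) and Bgn (6.72) beside Tnc, and with fibronectin, Fn1, lower (−2.04). Integrins and adhesion molecules rose in 11 of 19 and fell in 2 (12/2), Cdh11 (7.22), Cdh2 (5.94), Sdc2 (5.35) and Itga11 (4.46) against Alcam (−1.72) and Itga6 (−1.02). BMP and TGF-beta signalling rose in 16 of 22 and fell in 3 (16/3), Fstl1 (7.20), Bmp6 (6.10) and Ltbp2 (5.99) against Id2 (−3.09), Tgfb1 (−2.79) and Id1 (−1.71). Wnt and Notch signalling rose in 16 of 25 and fell in 1 (16/1), with Ccn5 (4.60), Rspo3 (4.57) and Sfrp2 (4.47) higher and Notch1 lower (−0.70). The list test called all 5 of these and the reticular, niche, osteogenic and adipogenic lists higher. With an estimated correlation the niche (adjusted p = 0.0749) and BMP lists (adjusted p = 0.0580) lost that call.

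Lists of blood cells fell. All 18 measured B lineage genes were lower (0/18), with Vpreb3 (−6.40), Cd79b (−6.01), Cd79a (−5.97) and Jchain (−5.30), and so were all 11 erythroid genes (0/11), with Car1 (−6.64), Car2 (−5.34), Rhag (−4.30) and Ermap (−3.32). Neutrophil markers fell in 17 of 19 (0/18), with a median of −5.39, and all 26 cell cycle genes fell (0/26), with Ccnb2 (−5.15), Top2a (−5.15), Plk1 (−4.99) and Ccna2 (−4.98). These 4 lists also fell with an estimated correlation. Further lists fell at the preset correlation only, and the adjusted p with an estimated correlation, 0.0643 to 0.158, stands last in the parentheses. T and NK cell markers fell in 11 of 17 (0/13, 0.0734), with Nkg7 at −6.22, and monocyte and macrophage markers in 16 of 18 (1/16, 0.0904), with Lyz2 at −6.49. Megakaryocyte markers fell in 5 of 8 (0/5, 0.158), with Ppbp at −5.21 and Pf4 at −4.77. Mast cell, basophil and eosinophil markers fell in 9 of 10 (0/9, 0.0749), with Prg2 at −6.36, and all 8 MHC class II genes fell (0/8, 0.0643), with H2-Aa at −6.74 and Cd74 at −5.58.

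Lists of ribosomal, respiratory chain, hypoxia and immediate early genes were called lower as well. All 14 ribosomal protein genes fell (0/14), with a median of −1.22 and Rplp0 at −1.56 (adjusted p = 0.0755 with an estimated correlation), although Rps4x and Rps9 lay just above 0 and were not called after quantile or cyclic loess normalization. Nuclear genes of the mitochondrial respiratory chain fell in 14 of 19 (0/17), with Cox5a at −2.05 (0.0734). Hypoxia and glycolysis genes fell in 8 of 15 and rose in 1 (1/8), with Pgk1 (−2.38) and Egln3 (−2.35) against Vegfa (1.75, list 0.0755). Immediate early genes fell in 7 of 18 and rose in 1 (1/8), with Klf4 (−3.65) and Egr2 (−3.46) against Socs3 (2.50, list 0.498). After cyclic loess the hypoxia (adjusted p = 0.0683) and immediate early lists (0.102) were no longer called, and the filter on dim rows ended both calls too (0.176 and 0.0904).

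The remaining lists were not called. Chemokines and cytokines split, 7 higher and 5 lower of 18 (9/5), with Cxcl14 (6.30) and the T zone chemokine Ccl19 (5.72) against Cxcl2 (−6.64) and Il1b (−6.25). Smooth muscle and pericyte markers had 4 higher and 1 lower of 13 (4/1), Myl9 (3.69) and Notch3 (2.78) against Acta2 (−1.91), and were called higher only without YFP-positive replicate 3 (adjusted p = 0.0499) or with the filter on dim rows (0.0475). Schwann cell markers had 1 higher and 1 lower of 8 (1/1), S100b (5.60) and Mbp (−0.58). Haematopoietic progenitor markers had Hoxa9 higher (1.96) and 5 of 12 lower (1/5), with Myb at −5.08. Interferon response genes had 2 higher and 4 lower of 17 (4/4). Of 17 endothelial markers 0 were higher and 4 lower (0/2), with Pecam1 (−2.21) and Erg (−2.05); the median of the list was 0.07 although its mean (−0.23) and its test pointed down. The gate genes were called 3 higher and 1 lower (3/1).

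**Figure D3:**
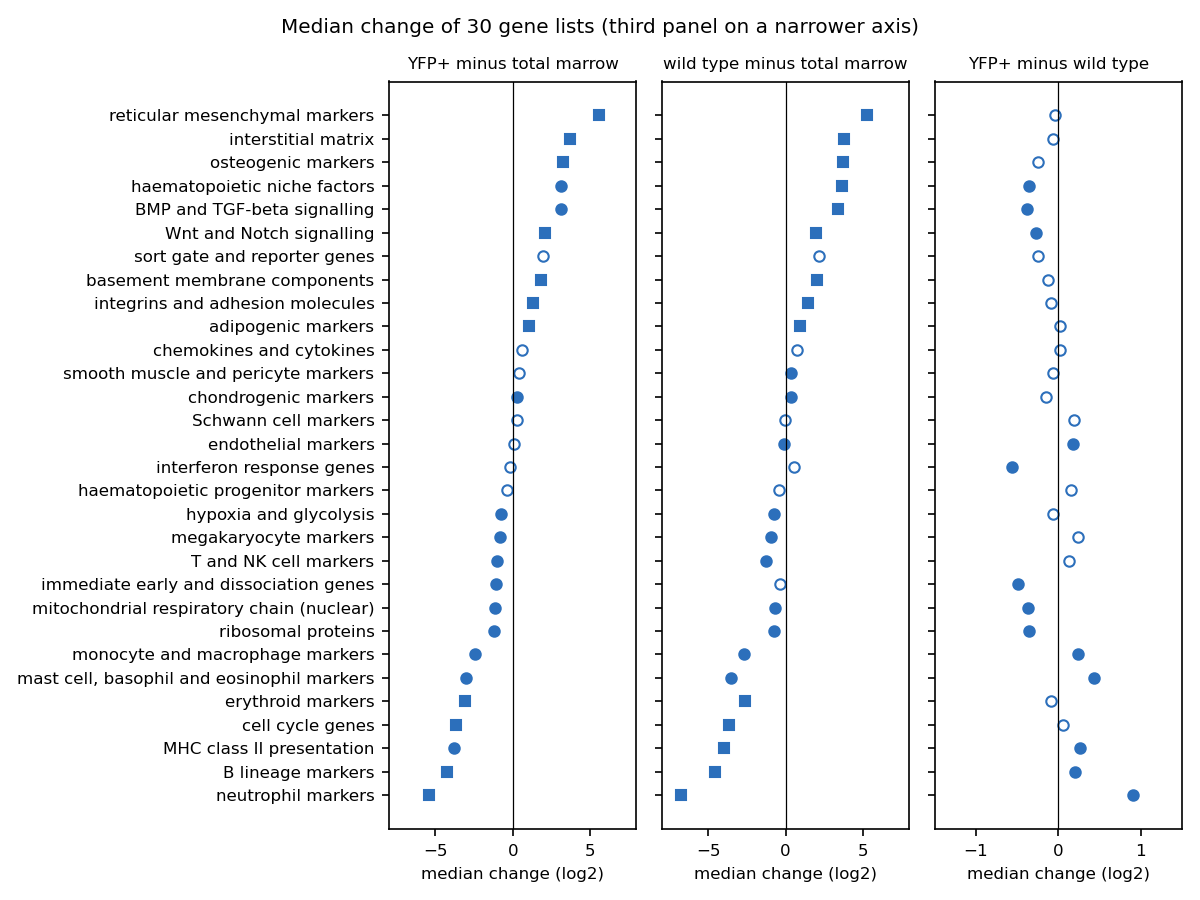
Median log2 change of the measured members of 30 gene lists in 3 comparisons of deposited values; filled symbols were called by camera at its preset correlation, and squares also with an estimated correlation. Stromal and matrix lists lie to the right in both comparisons with total marrow, and in the third panel, on a narrower axis, medians run from −0.57 to 0.91 with no square.

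Wild-type cells of the gate were compared with the same control, to ask what the gate holds without the reporter. The profile was again one of reticular stroma: Igfbp5 was higher by 8.41 ± 0.24 (SE, n = 3 and 2, adjusted p = 2.38e-07), as were Serping1 (7.85), Chrdl1 (7.68), Tnc (7.66), Cyp1b1 (7.64), the collagenase Mmp13 (7.63), Lepr (7.63), Sfrp4 (7.58), Fstl1 (7.56) and Islr (7.46). Lcn2 (−8.46), Lyz2 (−8.23), Chil3 (−8.18), Ngp (−8.03), Cd52 (−7.96), Ltf (−7.96), Ifitm6 (−7.81), Ly6g (−7.77), Camp (−7.65) and Mmp8 (−7.46) were lowest. Il7 was higher by 4.52 ± 0.38 (SE), Enpep by 3.31, Icam1 by 1.06, Nid1 by 5.20 and Nid2 by 4.50, and Ptprc was lower (−6.07). A total of 2269 rows were higher and 3022 lower, 1690 and 2131 of them by at least 2-fold. Without total marrow replicate 1 the total of 5291 fell to 3398. The 10 higher genes named first stood at 3.39 to 4.38 in total marrow, so their changes are lower bounds too.

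The lists were also tested in wild-type cells. Called higher were niche factors (12 of 15 higher, 13/0), reticular (13 and 1 lower of 16, 13/1), osteogenic (11 of 14, 11/0) and adipogenic markers (7 and 1 lower of 13, 7/1). Basement membrane (14 of 18, 14/0), interstitial matrix (17 of 23, 19/1), integrins (12 and 2 lower of 19, 12/2), BMP and TGF-beta (17 and 2 lower of 22, 19/3) and Wnt and Notch genes (17 and 1 lower of 25, 17/1) were called higher as well. Kitl (7.29), Cxcl12 (6.96) and Bmp4 (6.73) led the niche factors, Adipoq (7.16) the adipogenic and Sfrp1 (5.46) and Rspo3 (5.30) followed Sfrp4 among Wnt genes. These 9 held with an estimated correlation; chondrogenic markers (3 of 14, 3/0, adjusted p = 0.156) and smooth muscle and pericyte markers (4 of 13, 4/0, adjusted p = 0.0807) did not. Neutrophil (18 of 19, 0/19), B lineage (18 of 18, 0/18), erythroid (11 of 11, 0/11), MHC class II (8 of 8, 0/8) and cell cycle genes (26 of 26, 0/26) fell under both correlations.

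At the preset correlation only, 8 further lists fell in wild-type cells, here with the adjusted p under an estimated correlation last in the parentheses. They were T and NK cell (13 of 17, 0/16, 0.0504), monocyte and macrophage (16 of 18, 0/16, 0.0746), megakaryocyte (5 of 8, 0/5, 0.112), and mast cell, basophil and eosinophil markers (10 of 10, 0/10, 0.0504). Ribosomal proteins (11 of 14, 0/13, 0.122), respiratory chain genes (10 of 19, 0/12, 0.122), hypoxia and glycolysis genes (7 of 15, Vegfa higher, 2/8, 0.101) and endothelial markers (4 of 17, 0/4, 0.200) completed them. The endothelial call also ended without wild-type replicate 3 (adjusted p = 0.0503) or total marrow replicate 2 (0.0674), and the hypoxia call without YFP-positive replicate 3 (0.0544). The filter on dim rows ended both (0.0600 and 0.145). Not called were chemokines and cytokines (7 higher, 5 lower of 18, 9/5), interferon response (6 and 4 of 17, 8/4), immediate early (1 and 5 of 18, 1/5), progenitor (1 and 5 of 12, 1/5), Schwann cell (1 and 1 of 8, 1/1) and the gate genes (3 and 1 of 4, 3/1). The Schwann cell list had a median of −0.01 and a mean of 0.63, and its test pointed up. Immediate early genes were called lower without wild-type replicate 1 (adjusted p = 0.0468) or 2 (0.0300).

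Both comparisons named largely shared genes. Of the rows called higher, 1774 were higher in both sorted groups, where independent lists would share 249.5, and of those called lower, 2838 were shared, where independent lists would share 558. A single row went in opposite directions, Rpp38, a component of ribonuclease P (−0.89 in YFP-positive, 0.93 in wild type). The same 2 control arrays stand in both comparisons. With total marrow replicate 1 as the control of YFP-positive and replicate 2 as that of wild type, 1098 higher and 1758 lower rows were shared, where independent lists would share 90.9 and 250.1, and 3 rows went in opposite directions. Exchanging the replicates gave 1081 and 1834, where independent lists would share 83.0 and 237.8, and 0 opposite. From both controls together, 20 simulations of unchanged groups gave 0.05 shared rows on average. With no row truly changed in them, they do not measure how far shared controls raise the overlap. Without total marrow replicate 1 the shared counts were 1143 higher and 1777 lower, and without replicate 2 1149 higher.

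YFP-positive and wild-type cells were compared to ask whether the reporter-marked part of the gate differs from the gate as a whole; the genotype of the mice differs along with the reporter. Il7 differed by −0.61 (95% interval −1.41 to 0.19), Enpep by −0.59 (−1.53 to 0.34), Icam1 by 0.09 (−0.31 to 0.50), Ptprc by 0.10 (−0.12 to 0.33), Nid1 by −0.07 (−0.69 to 0.55) and Nid2 by −0.46 (−0.79 to −0.12), none of them called. No gene was called by limma (0 of 21789 rows, smallest adjusted p = 0.0680), while 3250 rows had an unadjusted p under 0.05, 1263 of them higher and 1987 lower. For 17665 rows (81.1%) the 95% interval lay within 1 log2 unit of 0. That share is over all rows tested, without a filter on intensity. The filter on dim rows keeps 12979 of them, and the share among those was not computed. Nearest to a call, and not called, were the myeloid peroxidase Mpo (2.93), the receptor P2ry14 (1.18), Phex (1.18), Tifa (1.02) and Cacng4 (0.68) on the higher side. On the lower side stood Smco3 (−1.80), the glutathione synthesis gene Gclm (−1.29), Slc35b3 (−1.08), Exoc3l4 (−1.07) and Tbcd (−0.90).

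The absence of calls rested on single arrays and on the moderation. Without YFP-positive replicate 1 the count was 26, 24 of them lower, with Smco3, Gclm and Exoc3l4 among them. That replicate was also the only YFP-positive array with low Xist, while every wild-type array had high Xist. Whether this difference bears on the absence of calls was not tested. Without replicate 2 it was 4 (Rbp4, Ctsc, Uxt and Nrep, all lower), without replicate 3 it was 1 (Mpo, higher), and without wild-type replicate 1 it was 1 (Smco3, lower). With trend and robust moderation 9 rows were lower, and over all rows of the file 1 unnamed row was higher.

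Lists moved by little between these groups, and every list call was lost with an estimated correlation. Interferon response genes were lower (0 of 17 called, 0/4), with a median of −0.57 and with Bst2 at −1.49 and Irf7 at −1.21 (adjusted p = 0.0854 with an estimated correlation). Neutrophil markers were higher (0 of 19 called, 4/0), with a median of 0.91 (adjusted p = 0.281). The YFP-positive arrays differed widely in these genes: Mpo stood at 7.80, 8.01 and 6.06 and S100a8 at 11.01, 9.21 and 4.36, while wild-type arrays held Mpo at 4.19, 4.14 and 4.76 and S100a8 at 9.29, 5.96 and 4.04. Small increases were called for monocyte and macrophage (0.25), mast cell, basophil and eosinophil (0.44), MHC class II (0.27), B lineage (0.20) and endothelial markers (0.18), with adjusted p from 0.304 to 0.509 when the correlation was estimated. The members of the MHC class II and endothelial lists that the rule names lay below the median of all values (4.43) in both groups. In YFP-positive and wild-type cells these were Cd74 (4.13 and 3.45), H2-Ob (3.90 and 3.42), Plvap (3.70 and 3.30) and Stab1 (4.04 and 3.79). Small decreases were called for niche factors (−0.35, 0.489), BMP and TGF-beta (−0.38, 0.281), Wnt and Notch (−0.28, 0.281), immediate early (−0.49, 0.567), ribosomal (−0.35, 0.281) and respiratory chain genes (−0.37, 0.281).

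After cyclic loess, 7 lists were called between these groups: the interferon list lower (−0.41), and the neutrophil, B lineage, monocyte and macrophage, mast cell, MHC class II and reticular mesenchymal lists higher. The reticular median changed sign, from −0.05 to 0.18 (adjusted p = 0.0250), and 0 of these 7 calls held with an estimated correlation (smallest adjusted p = 0.134). The niche, BMP, Wnt, endothelial, immediate early, ribosomal and respiratory chain calls on deposited values ended after cyclic loess. The other 17 lists were not called on deposited values with all arrays and rows. Under other settings T and NK cell markers were called higher without wild-type replicate 3 (adjusted p = 0.0457) or either total marrow array (both 0.0390), osteogenic markers lower without YFP-positive replicate 2 (0.0430) and megakaryocyte markers higher with the filter on dim rows (0.0285). That filter ended the niche (0.0958), Wnt (0.226), endothelial (0.0848) and immediate early calls (0.214), and camera on ranks ended the Wnt call (0.0812). Over the list alone, 1 osteogenic gene was higher and 1 lower. On the same basis 3 integrins, 2 interstitial matrix, 2 niche and 2 smooth muscle genes and 1 adipogenic, BMP, Wnt and immediate early gene each were lower. The reticular, adipogenic and chemokine lists had medians (−0.05, 0.02 and 0.02) or means (0.03, −0.04 and −0.03) that differ in sign from each other, with tests pointing down. Leaving out YFP-positive replicate 2 ended the B lineage (adjusted p = 0.0689), mast cell (0.243), MHC class II (0.0632), Wnt (0.0761) and immediate early calls (0.346), and leaving out replicate 3 ended the niche (0.0837), Wnt (0.0559), B lineage (0.183) and MHC class II calls (0.191). Without wild-type replicate 1 the Wnt and immediate early calls ended (both 0.0965), without replicate 2 the Wnt (0.0683), B lineage (0.108), mast cell (0.0683) and immediate early calls (0.134), and without replicate 3 the MHC class II call (0.143).

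YFP-negative cells were set against YFP-positive cells of the same gate, the comparison that the series title points to, to ask what separates cells of the gate without the YFP mark. After cyclic loess, a rescaling chosen after the data were seen, Il7 stood at 7.03, against 7.16 ± 0.65 (SD, n = 3) in YFP-positive cells, and was not called between them. As deposited Il7 stood at 5.87 against 7.21 and was called lower (−1.34, adjusted p = 0.0363), where the median change of all rows was −0.91, so the near-equality depends on the rescaling. Several of the genes with the largest increases belong to fibrous and cartilage matrix, while the interstitial matrix list was not called and the chondrogenic list only under some settings. Cytl1, a cytokine of cartilage (transcript cluster 10521537), was higher by 6.74 ± 0.89 log2 units (SE, n = 1 and 3, adjusted p = 0.0162), and asporin, Aspn (10405047), by 5.56 ± 0.16 (adjusted p = 4.18e-05). The microfibril gene Mfap5 (4.78), dermatopontin, Dpt (4.36), Igfbp6 (4.22), thrombospondin 4, Thbs4 (3.68), Ublcp1 (3.34), the procollagen enhancer Pcolce2 (3.33), Ormdl1 (3.27) and Cstad (2.99) were higher as well. Cytl1, Aspn, Mfap5, Dpt, Igfbp6, Thbs4 and Pcolce2 stood at 2.85 to 4.35 in YFP-positive cells, below the median of all values after cyclic loess (4.53). On that scale their changes are lower bounds and their order is not resolved. The size depends on the rescaling: in the YFP-negative array Aspn stood at 7.65 as deposited and at 8.41 after cyclic loess. Lower were the RNA components of ribonuclease complexes Rmrp (−3.89) and Rpph1 (−2.80), Mpo (−3.33), Oaz2 (−2.45), Plekha2 (−2.45), Ube2h (−2.30), Pcnx3 (−2.28), Xiap (−2.26), Tmem223 (−2.24) and Ndufa13 (−2.20). Il7 (−0.13 ± 0.43), Icam1 (0.20), Enpep (0.09), Ptprc (0.15), Nid1 (0.00 ± 0.31) and Nid2 (−0.70) were not called.

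After cyclic loess 570 rows were higher and 297 lower, against 1871 and 641 after median centring, 972 and 711 after quantile normalization, and 101 and 16421 as deposited, where the array's lower scale enters. From a fit on only the groups compared, none of the 867 was called (0 rows, unadjusted p under 0.05 in 4773 rows in the full fit), and the count was 236 or 240 without a total marrow array and 549 or 421 without wild-type replicate 1 or 2.

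**Figure D4:**
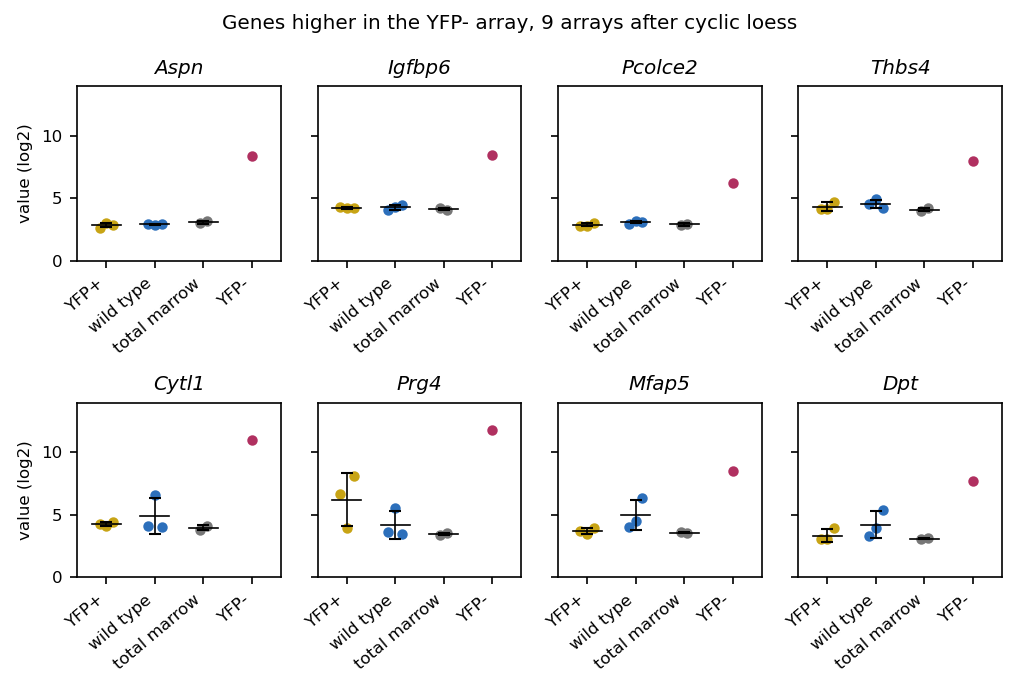
Log2 values after cyclic loess normalization of 8 genes in the 9 arrays; points are arrays, bars are group means with SD, and the YFP-negative group is a single point. Aspn, Igfbp6, Pcolce2 and Thbs4 stand at 8.41, 8.46, 6.23 and 8.02 in the YFP-negative array, while Cytl1, Prg4, Mfap5 and Dpt are also raised in some single arrays of the other sorted groups.

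Among lists, chondrogenic markers were called higher in YFP-negative than in YFP-positive cells (2 of 14 higher, 6/0), with a median of 0.61, Cytl1 and the proteoglycan Acan (0.87) called, and an adjusted p of 0.00513. The call ended with an estimated correlation (adjusted p = 0.342) and after median centring (adjusted p = 0.165). In the interstitial matrix list 4 of 23 were higher (5/2), Fmod (2.95), Dcn (0.88) and Fbln2 (0.80) beside Mfap5, and the list was not called. On deposited values it was called higher relative to all rows (adjusted p = 3.93e-05), with a median of −0.38 where the median of all rows was −0.91, and so were the chemokine (−0.85, adjusted p = 0.0262) and immediate early lists (−0.88, adjusted p = 4.59e-06). With an estimated correlation 0 lists were called on deposited values (smallest adjusted p = 0.136). Acan stood at 4.37 in the YFP-negative array and 3.50 in YFP-positive cells, both below the median of all values (4.53). The same held for Mmp8 (3.99 and 3.25) and Ppbp (4.23 and 3.07), named below, so the size of these 3 changes is not resolved. As deposited the sign turned for Acan (−0.00375) and Mmp8 (−0.51). Surface and signalling genes were called singly: the antigens Cd34 (2.58) and Thy1 (1.81), the eosinophil chemokine Ccl11 (2.40), the integrin Itga5 (1.43), and on the lower side Bmp6 (−1.14) and Ltbp2 (−1.30). Osteogenic markers had Omd (2.15) and Dmp1 (1.19) higher and Col1a2 lower (−0.81, list 3/1), and basement membrane components Col15a1 higher (0.63) and Agrn lower (−1.59, list 1/3). Neutrophil markers had Mmp8 higher (0.74) and Mpo and Cebpe (−0.80) lower (2/2), next to the unequal Mpo levels of the YFP-positive arrays. Ldha (1.39) and Ndrg1 (1.40) of the hypoxia list (4/0), Hspa1a (1.31) of the immediate early list (1/0) and Ppbp (1.17) of the megakaryocyte list (1/0) were higher, and Rps2 of the ribosomal list was lower (−1.91, 2/1). Over the list alone 2 reticular, 4 integrin, 1 chemokine, 2 BMP and 1 progenitor gene were higher and 1 integrin and 2 BMP genes lower.

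The other 16 lists had 0 called members against YFP-positive cells: gate genes, niche factors, adipogenic, Wnt and Notch, endothelial, smooth muscle, Schwann cell, erythroid, B lineage, T and NK cell, monocyte and macrophage, mast cell, MHC class II, cell cycle, interferon and respiratory chain genes. Lgr5 of the Wnt list stood at 2.45 (adjusted p = 0.0527), not called. The median, mean and test differed in sign for the reticular, erythroid, monocyte, interferon, ribosomal and respiratory chain lists, none of them called.

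Against wild-type cells, a comparison of reporter-negative cells with the gate as a whole, many of the genes with the largest increases were the same as against YFP-positive cells. The genotype of the mice differs along with the reporter here too. So does Xist, which as deposited stood at 4.38 in the YFP-negative array and averaged 9.32 in wild-type cells (−4.94). Neither difference can be told apart from the absence of YFP in this comparison. Prg4, lubricin of joint surfaces, was higher by 7.55 ± 1.45 (SE, n = 1 and 3, adjusted p = 0.0376), Cytl1 by 6.09, Aspn by 5.49 ± 0.16 (adjusted p = 4.59e-05), Igfbp6 by 4.15, Mfap5 by 3.51, Dpt by 3.48, Thbs4 by 3.46, the opioid precursor Penk by 3.14, Pcolce2 by 3.12 and Zdhhc15 by 2.95. Aspn (2.92), Pcolce2 (3.11), Penk (3.46), Prg4 (4.22), Dpt (4.23) and Igfbp6 (4.31) stood below the median of all values (4.53) in wild-type cells. On the loess scale this makes the changes of Aspn, Pcolce2, Penk and Igfbp6 lower bounds. Wild-type arrays spread widely in Prg4 (SD 1.13) and Dpt (SD 1.07), so their changes are not read that way. As deposited the changes of Prg4 (6.13), Aspn (4.75), Igfbp6 (2.97), Dpt (2.57) and Pcolce2 (2.44) were smaller, so their size depends on the rescaling. Lower were Rmrp (−3.67), Mrps18a (−2.86), Ube2h (−2.70), Ypel2 (−2.67), Pcnx3 (−2.57), Plekha2 (−2.49), Tmem86a (−2.44), Parp6 (−2.41), Tcirg1 (−2.28) and Ndufa13 (−2.27). Il7 (−0.55; −1.95 and called lower as deposited, adjusted p = 0.00945), Icam1 (0.47), Enpep (−0.31), Ptprc (0.29) and Nid1 (0.18) were not called, and Nid2 was lower (−0.90, adjusted p = 0.0461). Counts were 653 higher and 341 lower, against 3121 and 1337 after median centring, 1028 and 692 after quantile normalization, and 73 and 16280 as deposited. Only the groups compared gave 264 in all; single arrays left out gave 183, 278 or 366 (wild type 1, 2 or 3), 257 or 258 (total marrow) and 1763 (YFP-positive 3). The Nid2 call ended in 10 alternatives, including each wild-type replicate left out.

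The lists called higher against wild type were chondrogenic markers (2 of 14, 4/0, Acan 0.92, median 0.39, adjusted p = 0.602 with an estimated correlation), interstitial matrix (5 of 23, 8/3, Fmod 1.95, Dcn 1.73, Col6a3 1.63, median 0.73, adjusted p = 0.619) and B lineage markers (1 of 18, 3/0, Pou2af1 0.81, median 0.34, adjusted p = 0.623). Median centring ended all 3 calls, quantile normalization the latter 2 (adjusted p = 0.168 and 0.907), and leaving out total marrow replicate 1 or 2 did the same (0.0560 and 0.197, or 0.0547 and 0.174). Median centring called 3 other lists, Wnt and Notch and interferon genes lower (both adjusted p = 0.0262) and endothelial markers higher (0.0326). Cell cycle genes were called higher in 5 of the 8 fits without a replicate (0.0111 to 0.0452), neutrophil and MHC class II genes higher in 2 and 3 of them and interferon genes lower in 3. Deposited values called chemokines and cytokines (adjusted p = 0.0120), neutrophil markers (0.00511) and immediate early genes (0.00304) higher relative to all rows, and 0 lists with an estimated correlation (smallest 0.0869). On deposited values the B lineage median was −0.68 and not called, above the median shift of all rows. Pou2af1 stood at 4.39 in the YFP-negative array and 3.58 in wild-type cells, Acan at 4.37 and 3.45, and Mmp8 at 3.99 and 3.06. All lie below the median of all values (4.53), so the size of their changes is not resolved. As deposited the sign turned for Pou2af1 (−0.42), Mmp8 (−0.32), Vwf (−0.43), Kif20a (−0.52), Hdc (−0.66) and Hspa1a (−0.0260). Cd34 (2.57, list 1/0), Lgr5 (2.70, 1/0), Ccl11 (2.34, 1/0), Thy1 (1.79, 4/0), Omd (2.37, 4/1), Ndrg1 (1.72, 3/0), Hspa1a (1.38, 1/0), Vwf (0.82, 1/0), Mmp8 (0.93, 2/0), Kif20a (0.62, 4/0), Gata2 (1.33) and Hdc (0.70, 2/0) were called higher singly. Agrn (−1.88), Col4a1 (−1.14) and Nid2 of the basement membrane (1/4), Flt3l (−1.20, 1/2), Col1a2 (−0.86), Ltbp2 (−1.09, 2/2), Irf7 (−1.82) and Stat2 (−1.38, interferon 0/4) and Rps2 (−1.86, 2/1) were lower. The remaining lists had 0 called members, with 5 integrins higher and 2 lower, 1 megakaryocyte and 3 MHC class II genes higher and 2 respiratory chain genes lower over the list alone. Median, mean and test differed in sign for the gate, basement membrane, BMP, immediate early and hypoxia lists. Of the rows called against YFP-positive cells, 419 higher and 203 lower were called in the same direction against wild type, where independent lists would share 17.1 and 4.65 and simulations of unchanged groups shared 0. The single YFP-negative array is common to both comparisons and cannot be divided, so this overlap does not separate its group from anything else particular to that array. No row was truly changed in the simulations, so they do not measure how far the common array raises the overlap.

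Against total marrow, 9 of the 10 higher genes named for the YFP-negative array were also named for YFP-positive or wild-type cells, the exception being Prg4, and no list test was run. Sfrp4 was higher by 8.84 ± 0.32 (SE, n = 1 and 2, adjusted p = 2.27e-06), then Ibsp (8.74), Igfbp5 (8.59), Chrdl1 (8.57), Cyp1b1 (8.52), Serping1 (8.51), Lepr (8.35), Tnc (8.33), Prg4 (8.31) and Kitl (8.24). Lyz2 (−8.06), Chil3 (−8.01), Cd52 (−7.79), Ngp (−7.19), Ctsg (−7.17), Ly6g (−7.11), Mpo (−7.06), Ifitm6 (−7.02), Tyrobp (−7.00) and Ltf (−6.77) were lowest. Nid1 (5.50), Il7 (4.03), Nid2 (3.72), Enpep (3.04) and Icam1 (1.57) were higher and Ptprc lower (−5.80). Counts were 2839 higher and 2880 lower, against 5385 and 3602 after median centring, 3193 and 3007 after quantile normalization, and 882 and 14784 as deposited. A fit on only the groups compared called 8885. The 10 higher genes stood at 2.73 to 3.76 in total marrow after cyclic loess, so on that scale their changes are lower bounds. As deposited, where the array's lower scale enters, the changes were smaller, with Sfrp4 at 7.56, Ibsp at 7.48 and Lepr at 7.04. Their size therefore depends on the rescaling.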

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

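Tests of the rescalings, of Xist, of the granule genes and of divided controls were chosen after the results were seen, as was the statistic for the splits; the tests of single arrays and of small RNA rows were set before their own results, but after the calls they concern were seen. Interferon response genes stood out because the 2 sorted groups moved apart against total marrow: the list's median was −0.16 in YFP-positive and 0.53 in wild-type cells, neither called, and −0.57 between them (adjusted p = 0.0854 with an estimated correlation). Rows with no gene in the annotation lay outside the tests of the report: 189 of 12146 were higher than total marrow in both sorted groups, where 11.2 would be shared by independent lists of 527 and 257, and the largest change was 6.75; 410 were lower in both. Both comparisons share their controls; with 1 total marrow array for each, 76 or 79 were higher in both, where independent lists would share 2.22 or 1.51. Between YFP-positive and wild type, only 10 splits of the 6 arrays exist, too few for a share under 0.05. The real split was the 1 with the most rows at an unadjusted p under 0.05, 3250, the highest other had 1806, and no split called any gene.

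The YFP-negative array differed from YFP-positive cells in 867 rows after cyclic loess. Its other scale stays open as a cause. Of the 867, 769 were called in the same direction after both median centring and quantile normalization (514 of 570 higher, 255 of 297 lower). Both rescalings called more rows than cyclic loess and only realign the whole array, so this recurrence cannot exclude effects of the scale on single rows. As deposited only 395 were called in the same direction (98 of 570 higher, 297 of 297 lower), so most of the higher calls need some rescaling. A sex difference shared with YFP-positive replicate 1, which had the same low Xist, is argued against as the whole cause: over 1089 rows called without that array, it lay 0.190 of the way towards the YFP-negative array (median; bootstrap over rows 0.167 to 0.212), and replicates 2 and 3, treated alike, lay 0.128 and 0.115 of the way, so a part of the rows stays open. The spread of a single array stays open: each sorted array set against the other 2 of its group gave at most 284 (YFP-positive 3) and otherwise 46, 12, 0, 0 and 0, below the 867, but 7 single arrays cannot give a share under 0.05, and a fit on only the groups compared called 0. A batch of that array and the absence of the reporter cannot be told apart, so any reading of these genes as a property of YFP-negative cells may hold only if more arrays repeat it.

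Neutrophil granule genes were present in YFP-positive arrays at levels that differ between arrays and genes. Whole-marrow RNA carried into the sort may account for part of it: as a dilution of total marrow the list's medians were 0.989%, 1.36% and 0.212% in replicates 1 to 3, and 9, 8 and 4 of the 19 genes lay over 1 log2 unit away. Mpo corresponded to 8.15%, 9.51% and 1.92%, above those medians. Ly6g corresponded to 0.0198%, 0.00912% and 0.0722% and Mmp8 to 0.0755%, 0.0850% and 0.0672%, far below Mpo. S100a8 corresponded to 32.9%, 8.69% and −0.68%. The shares take wild-type cells as background, and S100a8 varies widely among those arrays, so the shares are rough. Mpo set against Ly6g and Mmp8, and the genes over 1 log2 unit away, argue against 1 dilution for all without excluding it. The other genes, 15 of 19 in replicate 3, do not go against it, so carried-over RNA stays open for a part of the pattern. Sorted leucocytes, which the CD45 gate would remove, also stay open: Ptprc lay −0.57, −0.78 and −0.17 from its predicted level, which goes against them, but each level was under 1 log2 unit above the 3.64 of Ptprc in wild-type cells (median), taken as its background, too near for the gaps to exclude them. Expression of these genes by the stromal cells themselves was not tested.

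Small non-coding RNA rows were low in the YFP-negative array beside Rmrp and Rpph1. Scaling by intensity is argued against as the whole cause: the median of 72 small RNA rows was −0.32 against YFP-positive after cyclic loess, where 10000 random sets matched on level gave −0.0984 to 0.129. It was −0.63 against wild type and −0.64 against total marrow. Between YFP-positive and wild type it was −0.05, itself just outside its random range of −0.0486 to 0.0700. Wild type against total marrow (0.0992) also lay outside its range of −0.0872 to 0.0884, and YFP-positive against total marrow (−0.00641) lay inside its range. The random sets may therefore understate the spread of such rows, which was not tested. A difference in RNA isolation or amplification of that array remains a candidate explanation, untested and tied to its batch. No biological explanation was tested.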

How the results depend on the processing

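Repeats of the settings from loess values and divided controls were added after the data were seen; all other settings were fixed earlier, and every one of them was run. Single genes were rerun where the report names them by its rule or where they are called list members. Against total marrow, 344 genes of YFP-positive cells kept direction and call in 5590 tests, lost the call in 246 and reversed in 4, and 339 genes of wild-type cells did so in 5536, 215 and 1. Of 26 genes of the YFP-negative array against total marrow, 1 test lost a call. Against YFP-positive (78 genes) and wild-type cells (72 genes), that array's genes lost the call in 211 and 249 tests and reversed in 4 and 7. Counts of the single YFP-negative array moved most, and where no cause is given, none was tested.

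Leaving out a replicate gave 3636 to 6622 rows for YFP-positive and 3398 to 5980 for wild type against total marrow, and 1143 to 1934 higher and 1777 to 3079 lower shared by both; the lowest follow from a single control array. With the controls divided, 1098 or 1081 higher and 1758 or 1834 lower were shared. Between YFP-positive and wild type it gave 0 to 26; all rows of the file gave 1 and trend with robust moderation 9. With an estimated correlation, lists called fell to 11 (YFP-positive against total marrow), 14 (wild type against total marrow) and 0 (YFP-positive against wild type, and YFP-negative against either of them), and cyclic loess gave 7 between YFP-positive and wild type.

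For the YFP-negative array, values run against YFP-positive, wild type and total marrow in that order. Deposited values gave 16522, 16353 and 15666; median centring 2512, 4458 and 8987; quantile normalization 1683, 1720 and 6200; cyclic loess 867, 994 and 5719. From deposited values a dim-row filter gave 8395, 9361 and 9371 and a 2-fold minimum 8811, 8700 and 9564. From loess values a dim-row filter gave 479 and 488 in the former 2 comparisons, and only the groups compared 0, 264 and 8885, with fewer arrays to estimate the spread. Against wild type, array weights gave 2091 and a 2-fold minimum 657. Leaving out a replicate gave 236 to 1231 against YFP-positive and 183 to 1763 against wild type. Lists called against YFP-positive were 0 after median centring and 4 as deposited; against wild type they were 1 after quantile normalization, 5 as deposited and 1 to 7 without a replicate.

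Reversals in the YFP-positive comparison with total marrow were Rps4x (0.0725 after quantile and 0.0492 after cyclic loess normalization) and Rps9 (0.0681 and 0.103), and in the wild-type comparison Rps4x after quantile normalization (0.0381), none called there; the cause was not tested. For the YFP-negative array all reversals were on deposited values, whose lower scale shifts every change down. Against YFP-positive they were Col15a1 (−0.49), Acan (−0.00375), Fbln2 (−0.26) and Mmp8 (−0.51), and against wild type Pou2af1 (−0.42), Kif20a (−0.52), Vwf (−0.43), Hspa1a (−0.0260), Hdc (−0.66), Mmp8 (−0.32) and Fbln2 (−0.0188).

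Replicate numbers did not pair the samples: deviations of same-numbered YFP-positive and wild-type arrays correlated across genes at −0.06, −0.03 and −0.01. Pairs of unlike number ran from −0.12 to 0.16, and a pairing under other numbers was not tested. With the replicate number as a block, counts against total marrow were 5403 (YFP-positive) and 4699 (wild type), and 0 between the 2. From loess values the block left 5 rows against YFP-positive (Hmcn1 in 2 rows, Aspn, Igfbp6 and Pcolce2) and 6 against wild type (the same with Penk); the block takes degrees of freedom, and the cause was not tested further.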

Other observations

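Prg4, Chad, Cytl1 and Mfap5, chosen after their values were seen, were raised in single arrays of the replicated sorted groups as well. After cyclic loess, Prg4 stood at 11.77 in the YFP-negative array, at 6.64, 3.96 and 8.10 in YFP-positive replicates 1 to 3 and at 3.63, 5.53 and 3.50 in wild-type replicates 1 to 3, against 3.39 and 3.53 in total marrow. Chad, which encodes chondroadherin of cartilage, stood at 10.79 in the YFP-negative array, at 7.14 in YFP-positive replicate 3 and at 6.63 in wild-type replicate 2, and between 3.97 and 4.62 in the other arrays. Cytl1 was at 6.58 in wild-type replicate 2 and Mfap5 at 6.35 in wild-type replicate 3. Aspn and Igfbp6 did not vary in this way: outside the YFP-negative array Aspn lay between 2.67 and 3.16 and Igfbp6 between 4.09 and 4.50.

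Sex-linked genes differed between arrays of the reporter strain. In deposited values Xist stood at 4.12 in YFP-positive replicate 1 and 4.38 in the YFP-negative array, and at 7.93 to 9.48 in the other 7 arrays. The Y-linked genes Kdm5d and Eif2s3y stood at 5.67 and 4.76 in YFP-positive replicate 1 and at 4.35 and 3.53 in the YFP-negative array, against 3.03 to 3.79 and 2.47 to 3.13 elsewhere. Another Y-linked gene, Uty, stood at 4.25 in YFP-positive replicate 1, and its place in the YFP-negative array depended on the scale: as deposited it was at 2.60, within the 2.58 to 3.24 of the others, and after cyclic loess at 3.18, above their 2.63 to 3.02. The labels used here give no sex of the mice.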
